A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

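Total RNA of the yeast strain BY4741 (MATa), wild type or without UPF1, was extracted with hot phenol from cultures in rich medium at 30 °C, grown to an OD600 of 0.5 and given 100 µg/ml cycloheximide (CHX) or DMSO for 15 min, per the labels' protocols. Per the same protocols, 1.5 µg RNA with 3 µl ERCC spike-in mix was incubated with 1 unit of Terminator exonuclease for 1 h at 30 °C before stranded libraries were made. There were 4 groups of 2 libraries, 8 in all. The submitters' processing notes name the R64 genome, Trim Galore, HISAT2 2.2.0, featureCounts 2.0.0 and DESeq2, without giving a role or an order for each.

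The authors deposited 1 table of normalized signal densities for 11844 features, with a column per library and a column per group. The group columns equal the mean of the libraries and were not used further. Neither the library factors nor the feature lengths were stated. For each feature a whole length was found at which all of its values are whole reads times 1 factor per library; 100.0% of positive values were whole within 0.001 reads. After random changes of 3%, 1 of 500 features tried still had such a length, so the densities were read as reads per nucleotide times a library factor. The recovered length equalled the RefSeq span for 13.5% of protein-coding genes, was above it for 85.9% and below it for 0.6%, so the lengths take in more than the coding part for most. Median ratios between libraries over the snoRNAs were close to 1, which is why the factors look set on snoRNAs. Values are reported as scaled reads per kb, the deposited density times 1000. Feature names were kept as deposited, and 6071 of them were matched to a RefSeq gene table for R64, from which gene coordinates were taken. Of the features, 78 were 0 in every library.

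Recovered reads per library were 2394737 and 1310994 in WT DMSO, 2680955 and 4688212 in WT CHX, 2949790 and 2170091 in upf1 DMSO, and 1789937 and 5689078 in upf1 CHX. These are reads assigned to the listed features, not all reads sequenced. The correlation of log values between the replicates of a group, across features, was 0.935 in WT DMSO, 0.954 in WT CHX, 0.947 in upf1 DMSO and 0.948 in upf1 CHX. With so few reads, a fold against a group without reads is given against 3 reads over that group, and a ratio against 1 to 3 reads with its exact 95% interval.

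Differences were tested with limma 3.58.1 in R 4.3.3 on log2 of the density plus 2 scaled reads per kb, the 10th percentile of the positive values. Features with a mean of at least 2 scaled reads per kb entered, 10392 in all, of which 5517 were protein-coding. The ribosomal RNA rows were left out of the test, and the table has no spike-in rows. All 8 libraries were fitted together, with a variance trend, 4 residual degrees of freedom and 3.60 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over all features of a comparison and a threshold of 0.05. The comparisons were CHX against DMSO in WT and in upf1, upf1 against WT in DMSO and in CHX, and the interaction of CHX with genotype. Classes and gene lists were tested with camera of limma, with a preset correlation of 0.01 and again with an estimated correlation, classes against the other features and lists against protein-coding genes. Camera compares test statistics, in which the SE enters, so its direction can differ from that of a median change. The adjustment ran over all classes and lists of a comparison. The comparisons, the test, the pseudocount and filter rules, the gene lists, the rule for named genes and all alternatives except voom were fixed before the data were examined.

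The 33 gene lists were NMD targets and regulators, NMD machinery, pyrimidine genes under Ppr1, cytoplasmic mRNA decay, nuclear exosome and early termination, cytosolic ribosomal proteins, ribosome biogenesis, RNA polymerase I and III, amino acid biosynthesis under Gcn4, methionine and sulfur assimilation, histones, G1/S genes, G2/M and M/G1 genes, environmental stress response, proteasome, pleiotropic drug resistance, glycolysis and fermentation, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, mitochondrial ribosomal proteins, phosphate regulon, iron regulon, ergosterol synthesis, unfolded protein response and ER chaperones, autoregulated short-lived mRNAs, MATa-specific, MATalpha-specific, haploid and pheromone genes, meiosis and sporulation genes, telomere maintenance, snRNAs, capped snoRNAs and snoRNAs with processed ends. They were written from general knowledge. Lists overlap in places, as do the transcript catalogues (NUTs with snoRNAs, XUTs with CUTs and SUTs), so counts of classes are not independent. Genes with near-identical copies (COS, AAD, PAU and HXT genes, histones, ribosomal protein pairs and tRNAs) were taken as uncertain, because the treatment of reads that map to several places is not stated. Overlapping features on a strand share reads as well.

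The genes named in the text are NAM7, the genes deleted in BY4741 (of which HIS3 is in the table; URA3, LEU2 and MET17 were not analysed here), and, per comparison, the 8 protein-coding genes with a standard symbol and the 4 non-coding features with the largest rise and with the largest fall. These had to be past the threshold with both replicates of a group above both of the other. Up to 4 members of each list with the smallest p were added, and where no feature passed, the 4 with the smallest p. Not every gene that the rule names is printed.

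The alternatives were a replicate block, leaving out each library in turn, a pseudocount 4 times as large or 0.25 times as large, no low-value filter or 4 times its value, median scaling over protein-coding genes, quantile normalization, no variance trend, robust variance estimates, and only the 4 libraries of a comparison. Voom of limma on the recovered reads was added after the data were seen. For each comparison the test was also run on simulated data with known changes. For CHX in WT, over 10344 features, it found 5 of 50 features changed 2-fold, 28 of 50 changed 4-fold and 40 of 50 changed 8-fold, and called 0 of 10146 unchanged features. For upf1 against WT in DMSO, over 10296 features, it found 1 of 50, 21 of 50 and 40 of 50, and called 8 of 10097 unchanged. Few features changed in the simulated data and no shift of all was added. The shares found are therefore not the sensitivity of a comparison in which most features rose, as on CHX. Each feature was simulated at its mean density over the 8 libraries, with a spread taken from well-read features. By the protein-coding median the DMSO libraries lay below that level. The shares may thus be too high for comparisons that use DMSO libraries. Chance overlap of comparisons with shared controls was simulated 50 times.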

Results

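Terminator, an exonuclease that degrades RNA with a 5′ monophosphate and spares capped RNA, was applied to total RNA of the budding yeast strain BY4741 (MATa) before stranded sequencing. Wild-type cells (WT) and cells without UPF1, the helicase of nonsense-mediated decay (NMD, the translation-coupled decay of RNAs with early stop codons), had received cycloheximide (CHX, a blocker of translation elongation) or its solvent DMSO for 15 min. The 4 groups held 2 biological replicates each. Undigested libraries of these cultures were not analysed here, so a higher value may be read as more of an RNA or as a larger capped share of it. The libraries held 2394737 and 1310994 reads in WT DMSO, 2680955 and 4688212 in WT CHX, 2949790 and 2170091 in upf1 DMSO, and 1789937 and 5689078 in upf1 CHX. A protein-coding gene had a median of 11 and 7 reads in the WT DMSO libraries, 29 and 41 in WT CHX, 27 and 17 in upf1 DMSO, and 30 and 101 in upf1 CHX. Over all 1628 XUTs (transcripts sensitive to the exonuclease Xrn1) these medians were 1 and 0, 5 and 7, 3 and 2, and 4 and 13. Changes of single XUTs against WT DMSO therefore start from few reads. Values are given in scaled reads per kb, the deposited density times 1000, as the mean ± SD of 2 libraries, and changes as log2 ± SE. The log2 scale carried an added 2 scaled reads per kb, which understates the change of weakly read genes.

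UPF1 itself, listed as NAM7 (YMR080C, R64 chromosome XIII, 426712 to 429627), was read in every library. It stood at 14.8 and 15.2 in WT DMSO, 83.5 and 44.8 in WT CHX, 5.94 and 2.80 in upf1 DMSO, and 13.5 and 10.1 in upf1 CHX, so each upf1 library lay below each WT library. NAM7 fell by 1.46 ± 0.386 in upf1 against WT in DMSO (limma adjusted p = 0.0439). In CHX its change of -2.21 ± 0.386 did not pass (adjusted p = 0.113). The DMSO call ended when any 1 of the 8 libraries was left out. The upf1 libraries kept 25, 10, 25 and 66 reads of the gene, and the labels do not state which part of it was deleted.

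Coding RNA took a larger share of the reads after CHX. Protein-coding genes held 53.1% and 53.5% of the reads in WT DMSO and 71.0% and 67.2% in WT CHX, against 58.8% and 56.5% in upf1 DMSO and 72.5% and 71.3% in upf1 CHX. SCR1, the RNA of the signal recognition particle, held 17.7% and 17.1% in WT DMSO, 9.41% and 11.1% in WT CHX, 13.2% and 11.4% in upf1 DMSO, and 7.61% and 6.63% in upf1 CHX. Summed over a class, protein-coding genes went from 1177 ± 15.7 to 2188 ± 158 units of 1000 scaled reads on CHX in WT, a log2 change of 0.89 ± 0.075. XUTs, which are transcripts degraded by the cytoplasmic exonuclease Xrn1, went from 3.85 ± 0.332 to 19.99 ± 2.02 in WT and from 12.6 ± 1.94 to 28.9 ± 0.908 in upf1. SUTs, the stable unannotated transcripts, moved alike, from 2.47 ± 0.308 to 13.1 ± 1.68 in WT and from 7.86 ± 1.47 to 19.4 ± 0.901 in upf1. CUTs, which the nuclear exosome degrades, stood at 2.57 ± 0.35 in WT DMSO and 2.97 ± 0.194 in upf1 DMSO. Their sums with CHX were 8.03 ± 0.787 in WT and 6.73 ± 0.108 in upf1. snoRNAs, on which the deposited library factors look set, changed by -0.25 ± 0.074 on CHX in WT and by -0.06 ± 0.033 in upf1 against WT in DMSO.

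**Figure D1:**
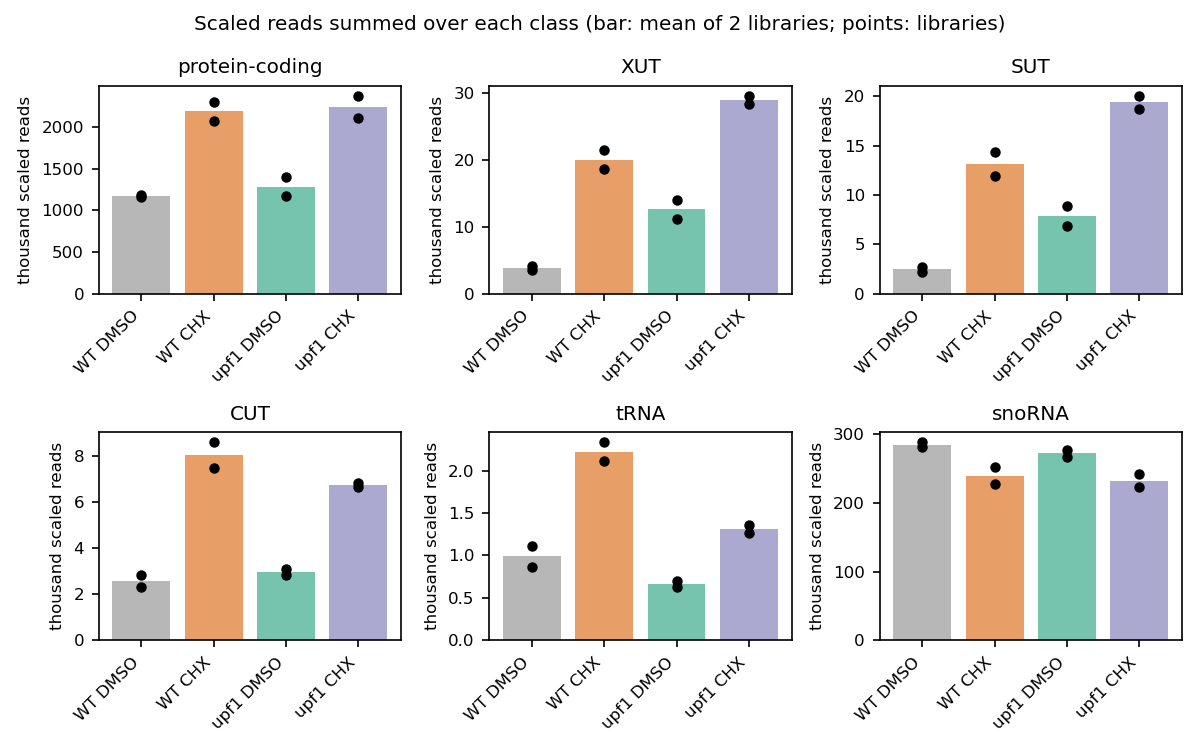
Scaled reads summed over each transcript class, in units of 1000, in the 4 groups; bars are means of 2 libraries and points are the libraries. XUT sums stood at 3.85 in WT DMSO, 12.6 in upf1 DMSO, 19.99 in WT CHX and 28.9 in upf1 CHX.

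Which RNAs of the digested samples stood higher when elongation was blocked was asked first in WT. A higher value here may be a larger amount, a larger capped share or less complete digestion, on library factors that look set on snoRNAs. Of 5517 protein-coding genes tested, 3779 rose on CHX and 1 fell, with a median log2 change of 1.23, or 2.35-fold. Among non-coding classes, 1037 of 1373 XUTs, 548 of 705 SUTs, 520 of 756 CUTs and 1000 of 1243 NUTs (Nrd1-unterminated transcripts) rose. Summed over the class, NUTs went only from 167.8 to 180.7 units of 1000 scaled reads, by 0.106 ± 0.031 (1.08-fold). Over all 10392 features tested, 7257 rose and 11 fell by limma. With each library set to a common protein-coding median, which took 1.24 off the changes, 947 were higher and 305 lower, and with quantile normalization 628 were higher and 551 lower. Without WT CHX replicate 1 the rises numbered 4738, and without WT CHX replicate 2 the falls numbered 25. The gene-list results that follow are therefore given relative to the protein-coding median.

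CIT2 (YCR005C, chromosome III, 120946 to 122328), the peroxisomal citrate synthase, went from 14.4 ± 8.43 to 2979 ± 596 scaled reads per kb, a log2 change of 7.59 ± 0.505 (limma adjusted p = 0.000274). NRG1 (YDR043C, chromosome IV, 542674 to 543369), a glucose repressor, went from 3.27 ± 0.394 to 184 ± 20.5, by 5.14 ± 0.226 (adjusted p = 0.000102). SPO24 (YPR036W-A, chromosome XVI, 645950 to 646153), a short sporulation gene, went from 362 ± 12.7 to 11340 ± 1280, by 4.96 ± 0.195 (adjusted p = 6.42e-05). ICY1, DPI8, ARO10 (the decarboxylase of aromatic amino acid breakdown) and TPO4 (a polyamine exporter) rose by 4.61, 4.46, 4.27 and 4.11. PAU5, of a seripauperin family with near-identical copies, had 29 reads in WT CHX and 0 in WT DMSO and was at least 6.89-fold higher, a call that remains uncertain. GND1 (YHR183W, chromosome VIII, 470960 to 472429), the phosphogluconate dehydrogenase, was the protein-coding gene that fell, from 649 ± 18.1 to 404 ± 5.01, by 0.68 on the log2 scale (adjusted p = 0.00827). HIS3, NAM7, DAL7, COX19 and CPA1 rose by 2.44, 1.90, 3.11, 2.67 and 1.56; the calls of NAM7 and CPA1, and that of tD(GUC)N, ended with median scaling. Of the non-coding features, CUT180 had 58 reads against 2, a ratio of 20.7 (95% interval 5.47 to 175). tD(GUC)N had 48 against 2, a ratio of 17.1 (4.49 to 145). tV(AAC)G2 and tV(AAC)K2 were at least 3.33-fold and 3.09-fold higher. The falls of tM(CAU)J1 (2 reads against 0), XUT1149 (11 against 4) and CUT034 (8 against 3, a ratio of 3.74 with an interval of 0.898 to 21.9) rested on few reads. tI(UAU)D fell by 1.03. The calls of XUT1149, CUT034 and tI(UAU)D ended without WT DMSO replicate 1, WT DMSO replicate 2 or WT CHX replicate 1. The call of XUT1149 also ended without either upf1 CHX library, and that of CUT034 without either upf1 DMSO library. tRNA copies share reads, and these intervals and floors (3 reads over a group) cover counting error only.

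All 10 histone genes tested rose on CHX in WT, with a list median 0.83 above the protein-coding median (camera adjusted p = 0.0141, and adjusted p = 0.809 with an estimated correlation); HHT1 and HTB2 rose by 2.32 and 2.11. In the phosphate regulon 14 of 16 genes rose, with a median 0.45 above (adjusted p = 0.0141, and adjusted p = 0.809 with an estimated correlation). SPL2, PHO89, PHO5 and PHO84 rose by 3.69, 3.06, 2.66 and 1.81. Amino acid genes under Gcn4 rose in 33 of 35 cases, with a relative median of 0.35 (adjusted p = 0.0141, and adjusted p = 0.809 with an estimated correlation), and TRP4 and LYS4 rose by 2.21 and 2.18. In the iron regulon 23 of 24 genes rose, with a relative median of 0.31 (adjusted p = 0.0141, and adjusted p = 0.809 with an estimated correlation), and MRS4 and FET3 rose by 2.25 and 1.34. Cytosolic ribosomal protein genes rose in 133 of 137 cases but lay only 0.11 above the median (adjusted p = 0.0248, and adjusted p = 0.938 with an estimated correlation); RPL22B and RPS14B rose by 3.10 and 1.81. Ribosome biogenesis genes lagged, with 41 of 93 higher (32 adjusted over the list alone), a relative median of -0.40 and adjusted p = 0.00062 (0.809 with an estimated correlation). Proteasome genes lagged as well, with 14 of 33 higher (9 adjusted over the list alone), a relative median of -0.53 and adjusted p = 0.000211 (0.809 with an estimated correlation). Glycolysis and fermentation genes had 16 of 27 higher, a relative median of -0.39 and adjusted p = 0.00718 (0.809 with an estimated correlation), and quantile normalization turned the median to 0.28 (adjusted p = 0.417). Their members of small p were UTP15 and PWP2, PRE8 and PRE5, and ADH2 and CDC19, at 1.76 and 1.58, 1.79 and 1.87, and 3.12 and 0.93, so all but CDC19 lay above the protein-coding median. With median scaling CDC19 stood at -0.31, and the calls of UTP15, PWP2, PRE8, PRE5, PHO84, RPS14B and FET3 ended. By limma 0 of 5 mitochondrially encoded genes were called, 0 without adjustment and 0 by voom, at a relative median of -0.80 (adjusted p = 0.00062, and adjusted p = 0.363 with an estimated correlation). Without WT DMSO replicate 1 camera no longer called the ribosomal protein, histone, phosphate or glycolysis lists. The calls of ribosome biogenesis and iron genes ended without WT DMSO replicate 2, those of ribosomal proteins and glycolysis without WT CHX replicate 1, and that of ribosome biogenesis without WT CHX replicate 2. The ribosomal protein call also ended without either upf1 CHX library. For the lists of protein-coding genes in the paragraphs on CHX in WT, CHX in upf1 and upf1 in DMSO, but not for the classes or the lists of snoRNAs, a count for the list alone that is not given equalled the count over all features.

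snoRNAs and snRNAs stood low relative to mRNA on CHX in WT, on factors that look set on snoRNAs, while XUTs, SUTs, CUTs and NUTs had medians of 1.80, 1.75, 1.78 and 1.59, above that of mRNA. The snoRNA class had 13 of 76 higher and 4 lower, with a relative median of -1.21 (camera adjusted p = 2.24e-37, and adjusted p = 0.00286 with an estimated correlation). snR13 fell by 0.66 and snR17a by 0.39, while snR62, snR71 and snR36 rose by 2.55, 2.04 and 0.74; with median scaling snR36 stood at -0.50 and the snR71 call ended. The call of snR17a ended without WT CHX replicate 1 or either WT DMSO library, and that of snR36 without WT DMSO replicate 2 or WT CHX replicate 2. Capped snoRNAs, snoRNAs with processed ends and the 6 snRNAs had relative medians of -1.46, -0.94 and -1.39 (adjusted p = 4.02e-32, 9.38e-15 and 1.62e-11). Each of these 3 lists had adjusted p = 0.1 with an estimated correlation. NUTs and SUTs stood above the other features (adjusted p = 0.00111 and 0.0203), not so with an estimated correlation (adjusted p = 0.809 and 0.852). The SUT call ended without WT DMSO replicate 2 (and without WT CHX replicate 2). Mitochondrial ORFs, 11 in number, and 9 other non-coding RNAs stood low (adjusted p = 6.51e-14 and 0.0141, and adjusted p = 0.1 and 0.361 with an estimated correlation), the latter not without WT DMSO replicate 1. The tRNA class had 66 of 235 higher and 2 lower, and its median and its test differed in sign. With quantile normalization camera placed it up (adjusted p = 0.421). The median, 1.52, lay above the protein-coding median while camera placed the class down (adjusted p = 4.22e-19, and adjusted p = 0.0851 with an estimated correlation). Camera compares test statistics, so this placing does not mean smaller changes of tRNAs. Over every comparison, the camera calls that hold with an estimated correlation were the snoRNA class in the 4 pairwise comparisons and the tRNA class in all of these but CHX in WT. The snoRNA class had an estimated correlation of -0.003, against 0.481 and 0.121 for the capped and processed snoRNA lists. As the factors look set on snoRNAs, the snoRNA class calls may rest on that scaling. The tRNA class calls rest on few reads per feature in the libraries of low depth. The 255 tRNA features, of a median length of 73 nt, held only 0.026% to 0.072% of the reads of a library.

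**Figure D2:**
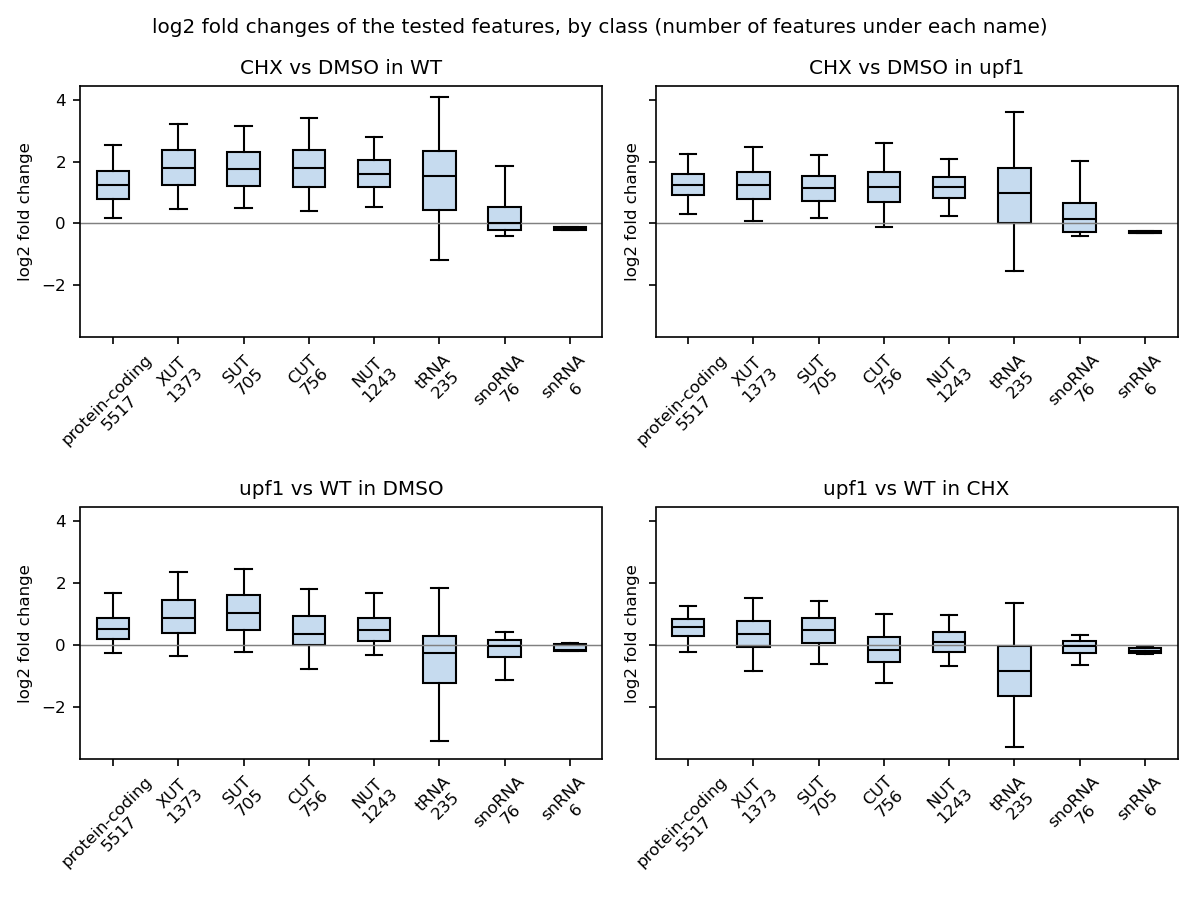
log2 fold changes of the tested features by class in each comparison, with the number of features under each class name; boxes show the median and quartiles. On CHX in WT the protein-coding median was 1.23 and the snoRNA median 0.02.

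In upf1 the protein-coding median moved on CHX by a similar amount, and XUT and SUT sums by less (2.31-fold and 2.49-fold, against 5.19-fold and 5.32-fold in WT). CHX raised 4083 of 5517 protein-coding genes and lowered 3, with a median change of 1.25 (2.37-fold). It raised 750 of 1373 XUTs, 388 of 705 SUTs, 345 of 756 CUTs and 795 of 1243 NUTs. Over all features 6666 rose and 16 fell by limma. Median scaling took off 1.25 and left 160 higher and 151 lower, and quantile normalization left 186 and 120. The rises numbered 3273 without upf1 DMSO replicate 2, 2439 without upf1 CHX replicate 1 and 4062 without upf1 CHX replicate 2. The falls numbered 10 without WT CHX replicate 1, 5 without upf1 DMSO replicate 2, 1 without upf1 CHX replicate 1 and 54 without upf1 CHX replicate 2. Of the features higher on CHX in upf1, 84.6% were also higher on CHX in WT, 5640 in number where independent lists would share 4655. These comparisons share no library but share the fitted variance of each feature, so 4655 is only a rough guide. Fold changes correlated across features with r = 0.465, and features are not independent replicates.

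CIT2 again led in upf1, from 26.8 ± 18.8 to 4341 ± 443, a log2 change of 7.41 ± 0.505 (limma adjusted p = 0.000878). NRG1, SPO24, ICY1, ARO10 and DPI8 followed at 5.35, 4.46, 4.39, 4.21 and 4.11. MPC3, a mitochondrial pyruvate carrier, had 62 reads against 1, a ratio of 57.4 (95% interval 9.92 to 2302). COX26, of the respiratory supercomplex, rose by 4.15. GND1 fell by 0.66, SAM1 (a methionine adenosyltransferase) by 0.55 and TDH2 (glyceraldehyde-phosphate dehydrogenase, close in sequence to TDH3) by 0.41. The GND1 call ended without upf1 DMSO replicate 2 or upf1 CHX replicate 1, and that of SAM1 without either upf1 CHX library. The TDH2 call ended without any 1 of the libraries except upf1 DMSO replicate 2 and the WT CHX pair. XUT1223 had 40 reads against 0 and was at least 12.3-fold higher. tY(GUA)D and tN(GUU)K were each at least 2.47-fold higher, and tE(UUC)G3 had 16 reads against 1. The falls of tE(UUC)J, tK(CUU)M, tG(CCC)O and tT(AGU)D rested on at most 5 reads per group. Each of these calls ended without either WT CHX library, either upf1 DMSO library or upf1 CHX replicate 1. The calls of tE(UUC)J and tK(CUU)M also ended without upf1 CHX replicate 2, and that of tT(AGU)D without either WT DMSO library. With median scaling these 4 calls and that of tE(UUC)G3 ended.

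The environmental stress list had 37 of 41 genes higher and a relative median of 0.33 (camera adjusted p = 0.00151, and adjusted p = 0.831 with an estimated correlation), with TPS2, TSL1, SOL4 and HOR7 at 3.19, 3.02, 3.31 and 2.46. G2/M and M/G1 genes had 20 of 22 higher at 0.33 (adjusted p = 0.0326, and adjusted p = 0.831 with an estimated correlation), with DSE4 and SCW11 at 2.52 and 1.91. Histones had 10 of 10 higher at 0.55 (adjusted p = 0.0432, and adjusted p = 0.831 with an estimated correlation), with HTA1 and HHT1 at 2.44 and 2.21. The iron regulon had 23 of 24 higher (24 adjusted over the list alone) at 0.27 (adjusted p = 0.0084, and adjusted p = 0.831 with an estimated correlation), with VHT1 and ISU2 at 2.63 and 1.66. All 16 phosphate genes rose, at 0.44 (adjusted p = 0.000326), with SPL2 and PHO89 at 3.65 and 3.09, and all 7 MATa-specific genes rose, at 0.71 (adjusted p = 0.00983), with STE2 and MFA2 at 2.05 and 1.96. Both had adjusted p = 0.622 with an estimated correlation. Glycolysis and fermentation genes stood low, with 13 of 27 higher and 1 lower, at -0.78 (adjusted p = 2.55e-08, and adjusted p = 0.521 with an estimated correlation), although PYK2 and ADH2 rose by 2.99 and 2.71. ER chaperone genes had 6 of 13 higher, at -0.70 (adjusted p = 0.0293, and adjusted p = 0.631 with an estimated correlation). FPR2 and HRD1 rose by 1.10 and 1.74, calls that ended without upf1 CHX replicate 1, and with median scaling FPR2 stood at -0.15. Ribosome biogenesis had 52 of 93 higher (51 adjusted over the list alone), at -0.29 (adjusted p = 0.00144, and adjusted p = 0.831 with an estimated correlation), with PWP2 at 1.44. The proteasome had 21 of 33 higher, at -0.41 (adjusted p = 0.0296, and adjusted p = 0.831 with an estimated correlation), with PRE8 at 1.23, which median scaling put at -0.02. The calls of SCW11, HHT1, MFA2, ISU2, PWP2 and HRD1 ended with median scaling.

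Single libraries decided several of these list results in upf1. Without upf1 CHX replicate 2 camera no longer called the histone, G2/M, ER chaperone or MATa-specific lists. The histone call also ended without upf1 CHX replicate 1, upf1 DMSO replicate 2 or either WT DMSO library, and the G2/M call without either WT CHX library. The ER chaperone call ended without upf1 DMSO replicate 1 and the proteasome call without upf1 DMSO replicate 2. The mitochondrially encoded genes had 0 of 5 called by limma, 0 without adjustment and 0 by voom, and stood at -0.98 (adjusted p = 1.56e-07, and adjusted p = 0.139 with an estimated correlation). Protein-coding genes as a class stood above the other features (adjusted p = 0.000266, and adjusted p = 0.831 with an estimated correlation). Camera placed CUTs down (adjusted p = 0.00185, and adjusted p = 0.622 with an estimated correlation), though their relative median was only -0.064. The snoRNA class had a relative median of -1.11 (adjusted p = 2.12e-32) and the tRNA class, with 45 of 235 higher and 5 lower, one of -0.25 (adjusted p = 1.61e-27). snR62 rose by 2.27 on CHX in upf1. snR13 fell by 0.48 and LSR1, the U2 spliceosomal RNA, by 0.42, and the snR13 call ended without upf1 CHX replicate 1 or upf1 DMSO replicate 2. The LSR1 call ended without upf1 CHX replicate 2, and with quantile normalization its change was 0. Capped snoRNAs stood at -1.50 (adjusted p = 6.22e-42, and adjusted p = 0.0744 with an estimated correlation). Processed snoRNAs stood at -0.87 (adjusted p = 7.69e-18, and adjusted p = 0.0746 with an estimated correlation), and snRNAs at -1.54 with the same preset value and adjusted p = 0.0744 with an estimated correlation. Other ORFs had a median 0.20 above that of protein-coding genes while camera placed them down (adjusted p = 0.0432, and adjusted p = 0.521 with an estimated correlation). With median scaling and with quantile normalization camera placed them up (adjusted p = 0.0256 and 0.0373). The call ended without either CHX library of either genotype and without upf1 DMSO replicate 2. Mitochondrial ORFs and other non-coding RNAs stood low (adjusted p = 5.99e-19 and 0.0112, and adjusted p = 0.0744 and 0.317 with an estimated correlation), the latter not without upf1 CHX replicate 2.

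**Figure D3:**
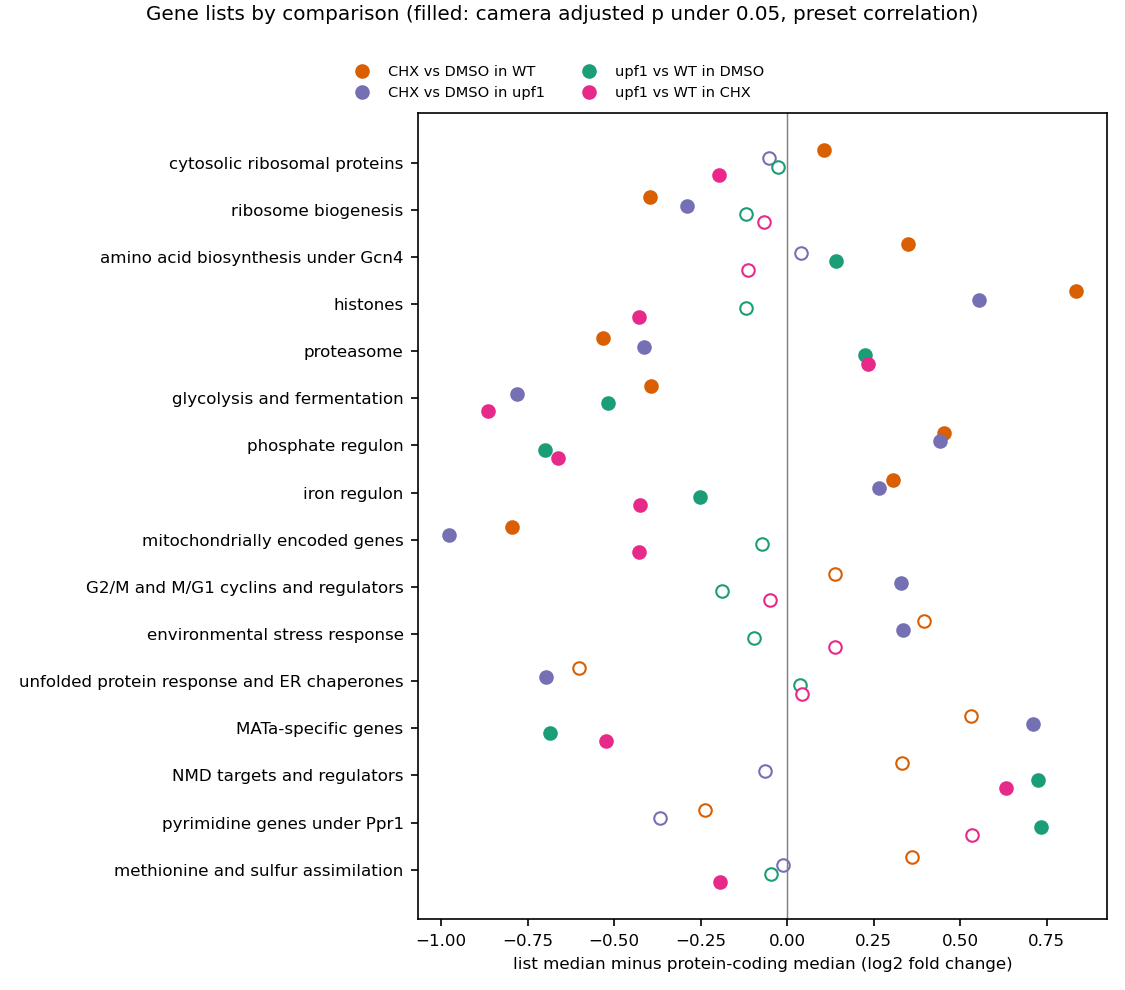
Median log2 fold change of each gene list minus the protein-coding median, by comparison; filled points passed camera with the preset correlation. Histones stood 0.83 above the median on CHX in WT. Glycolysis genes stood at -0.86 in upf1 against WT in CHX, and at -0.31 with a fitted trend with abundance removed.

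Which RNAs stood higher without NMD was asked in DMSO. Here 726 of 5517 protein-coding genes rose and 14 fell in upf1, with a median change of 0.51 (1.42-fold). Summed over the class the change was 0.12 ± 0.133 (1.09-fold), within its SE of 0. Among XUTs 327 of 1373 rose, and among SUTs 233 of 705. Among CUTs 44 of 756 were higher and 3 lower, and of 235 tRNAs 5 were higher and 19 lower. Over all features 1524 rose and 41 fell by limma. Median scaling took off 0.56 and left 367 higher and 92 lower, and quantile normalization left 295 and 79. A fit of only the 4 DMSO libraries gave 114 higher and 12 lower, and a pseudocount 4 times as large 827 and 27; without a variance trend 26 were lower. The rises dropped to 194 without upf1 DMSO replicate 1, 983 without upf1 DMSO replicate 2, 775 without WT DMSO replicate 2, 770 without upf1 CHX replicate 1 and 780 without upf1 CHX replicate 2. The falls numbered 17 without WT DMSO replicate 1, 11 without upf1 DMSO replicate 1, 23 without upf1 DMSO replicate 2, and 26 without upf1 CHX replicate 1 or upf1 CHX replicate 2. Of the features that rose, 97% also rose on CHX in WT, 1479 in number. Independent lists would share 1064. In 50 simulations all 8 libraries, the WT DMSO controls among them, were drawn as unchanged with the fitted variance of each feature. The comparisons then shared 0 calls. Unchanged groups yield hardly any calls, so this 0 is no measure for the overlap. The covariance of fold changes was 0.303 against 0.109 simulated, a difference of 0.194, and r, at 0.47, lay below the 0.501 simulated. The simulation gave every group the same spread. Replicates differed most in WT DMSO (SD of the difference 0.827, against 0.667 to 0.717 in the other groups). The simulated covariance may therefore be too low, and the excess of 0.194 too large. Without WT DMSO replicate 1 r was 0.626. Part of the excess of shared calls may come from the shared controls, whose 2 libraries are too few to divide between the comparisons.

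NBL1 (YHR199C-A, chromosome VIII, 498571 to 498859), a chromosomal passenger subunit, went from 12.2 ± 1.01 to 149 ± 34.0, by 3.39 ± 0.246 (limma adjusted p = 0.00229). DAL7 (YIR031C, chromosome IX, 413015 to 414679), a malate synthase, went from 3.85 ± 2.95 to 52.5 ± 20.1, by 3.27 ± 0.41 (adjusted p = 0.0054). NIT1, a nitrilase, had 96 reads against 3, a ratio of 23.4 (95% interval 7.76 to 115). MDJ2, a mitochondrial chaperone partner, had 35 against 1, a ratio of 25.6 (4.30 to 1038). COS12 had 122 against 3, a ratio of 29.7 (9.93 to 146). AAD14 had 64 against 1, a ratio of 46.8 (8.10 to 1875). AAD4 had 36 against 0, at least 8.77-fold higher. COS and AAD genes have near-identical copies, which leaves these values uncertain. SLO1 had 13 reads against 0, at least 3.17-fold higher. CUT361 had 12 against 0, at least 2.92-fold higher, and SUT638 had 36 against 1, a ratio of 26.3 (4.43 to 1067). tD(GUC)N had 29 against 2 and tG(CCC)O 5 against 0, while tK(CUU)E2, tY(GUA)D, tN(GUU)K and tS(AGA)D2 had 0 against 5, 7, 4 and 4. The tD(GUC)N call ended without either upf1 library of either treatment or either WT CHX library, and the tG(CCC)O call without either library of WT DMSO, WT CHX or upf1 DMSO. Both calls ended with median scaling.

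FIT3, a siderophore-binding wall protein, went from 171 ± 29.1 to 42.3 ± 13.5 in upf1 against WT in DMSO, by -1.99 ± 0.378 (limma adjusted p = 0.0166). TIR1 (a wall mannoprotein), PHO89 (a phosphate transporter) and HXT4 (a hexose transporter with close copies) changed by -1.66, -1.51 and -1.43. FIT2, SIT1 (siderophore uptake) and GLK1 (glucokinase) changed by -1.16, -0.94 and -0.89. All 7 of these calls ended without upf1 DMSO replicate 1. Those of FIT3, FIT2, SIT1 and GLK1 also ended without WT DMSO replicate 1 or upf1 DMSO replicate 2, and that of FIT2 without any 1 of the 8 libraries. Those of SIT1 and GLK1 ended as well without either upf1 CHX library, that of SIT1 without WT DMSO replicate 2, and that of GLK1 without either WT CHX library.

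The list of NMD targets and regulators rose in upf1, with 8 of 17 members higher (13 adjusted over the list alone) and a median 0.72 above the protein-coding median. Camera gave adjusted p = 3.3e-05, and adjusted p = 0.458 with an estimated correlation. CPA1 (YOR303W, chromosome XV, 882899 to 884134), whose upstream ORF makes its mRNA an NMD substrate, went from 49.9 ± 0.0901 to 219 ± 14.0, by 2.09 ± 0.177 (limma adjusted p = 0.00275). EST3, STN1 and COX19 rose by 2.57, 2.23 and 2.19. NMD4 and EBS1, of the NMD machinery list, rose by 2.65 and 1.61; the EBS1 call ended without any 1 of the libraries but WT DMSO replicate 2. The 3 pyrimidine genes tested of the Ppr1 list rose (camera adjusted p = 0.0439, and adjusted p = 0.513 with an estimated correlation), namely URA10, URA1 and URA4 at 1.61, 1.24 and 1.23. Their limma calls ended without upf1 DMSO replicate 1, and those of URA1 and URA4 also without WT DMSO replicate 1 or either upf1 CHX library. The URA4 call ended without WT DMSO replicate 2 as well, and the camera call without any 1 of the 4 DMSO libraries. Gcn4 amino acid genes had 8 of 35 higher (10 adjusted over the list alone) at 0.14 (adjusted p = 0.0476), with ARG8 and HIS5 at 2.18 and 2.00, and the proteasome 8 of 33 (10 adjusted over the list alone) at 0.23 (adjusted p = 0.048), with PRE5 and PRE10 at 1.40 and 0.98. Both had adjusted p = 0.93 with an estimated correlation, and both camera calls ended without WT DMSO replicate 1 or either upf1 CHX library. The Gcn4 call also ended without WT DMSO replicate 2, WT CHX replicate 2 or upf1 DMSO replicate 1, and the proteasome call without upf1 DMSO replicate 2. The limma calls of PRE5 and PRE10 ended without either WT DMSO library, either upf1 CHX library or upf1 DMSO replicate 1, and that of PRE10 without upf1 DMSO replicate 2. HIS3 rose by 1.40, and its call and that of ARG8 ended without upf1 DMSO replicate 1. With median scaling the calls of URA10, URA1, URA4, PRE5, PRE10 and EBS1 ended, as did that of FRE3 in the iron regulon.

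Phosphate genes lay under the protein-coding median in upf1, with 1 of 16 lower by test. The list had a relative median of -0.70 (camera adjusted p = 1.85e-08, and adjusted p = 0.466 with an estimated correlation). Glycolysis and fermentation genes had 1 of 27 lower at -0.52 (adjusted p = 1.01e-07, and adjusted p = 0.532 with an estimated correlation). Removing a fitted trend with abundance took that list to -0.31. MATa-specific genes had 1 of 7 lower, MFA1 at -0.87, and a relative median of -0.68 (adjusted p = 7.12e-05, and adjusted p = 0.513 with an estimated correlation). The iron regulon went both ways, with 3 of 24 higher (4 adjusted over the list alone) and 4 lower, at -0.25 (adjusted p = 0.00116, and adjusted p = 0.683 with an estimated correlation). FRE3 rose by 1.64 and FET3 changed by -0.70, and both calls ended without upf1 DMSO replicate 1, either WT DMSO library or either upf1 CHX library. The FET3 call also ended without upf1 DMSO replicate 2, and that of MFA1 without WT DMSO replicate 1 or either upf1 DMSO library. The camera call of the iron list ended without WT DMSO replicate 1. SUTs and XUTs stood above the other features (adjusted p = 1.11e-06 and 0.00189), not so with an estimated correlation (adjusted p = 0.559 and 0.689). The XUT call ended without WT DMSO replicate 2. CUTs stood low (adjusted p = 0.000125, and adjusted p = 0.532 with an estimated correlation), a call that ended without WT DMSO replicate 1. tRNAs had a relative median of -0.75 (adjusted p = 2.27e-28) and snoRNAs one of -0.55 (adjusted p = 1.34e-12). Capped and processed snoRNAs and snRNAs stood at -0.51, -0.80 and -0.69 (adjusted p = 0.000537, 1.12e-15 and 0.0022). With an estimated correlation these had adjusted p = 0.683, 0.204 and 0.532, and the capped snoRNA and snRNA calls ended without upf1 DMSO replicate 1. Quantile normalization turned the capped snoRNAs to 0.077 (adjusted p = 0.851). Other ORFs, at a relative median of -0.055, were placed down by camera (adjusted p = 0.000697, and adjusted p = 0.397 with an estimated correlation). That call ended without upf1 DMSO replicate 1 as well.

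**Figure D4:**
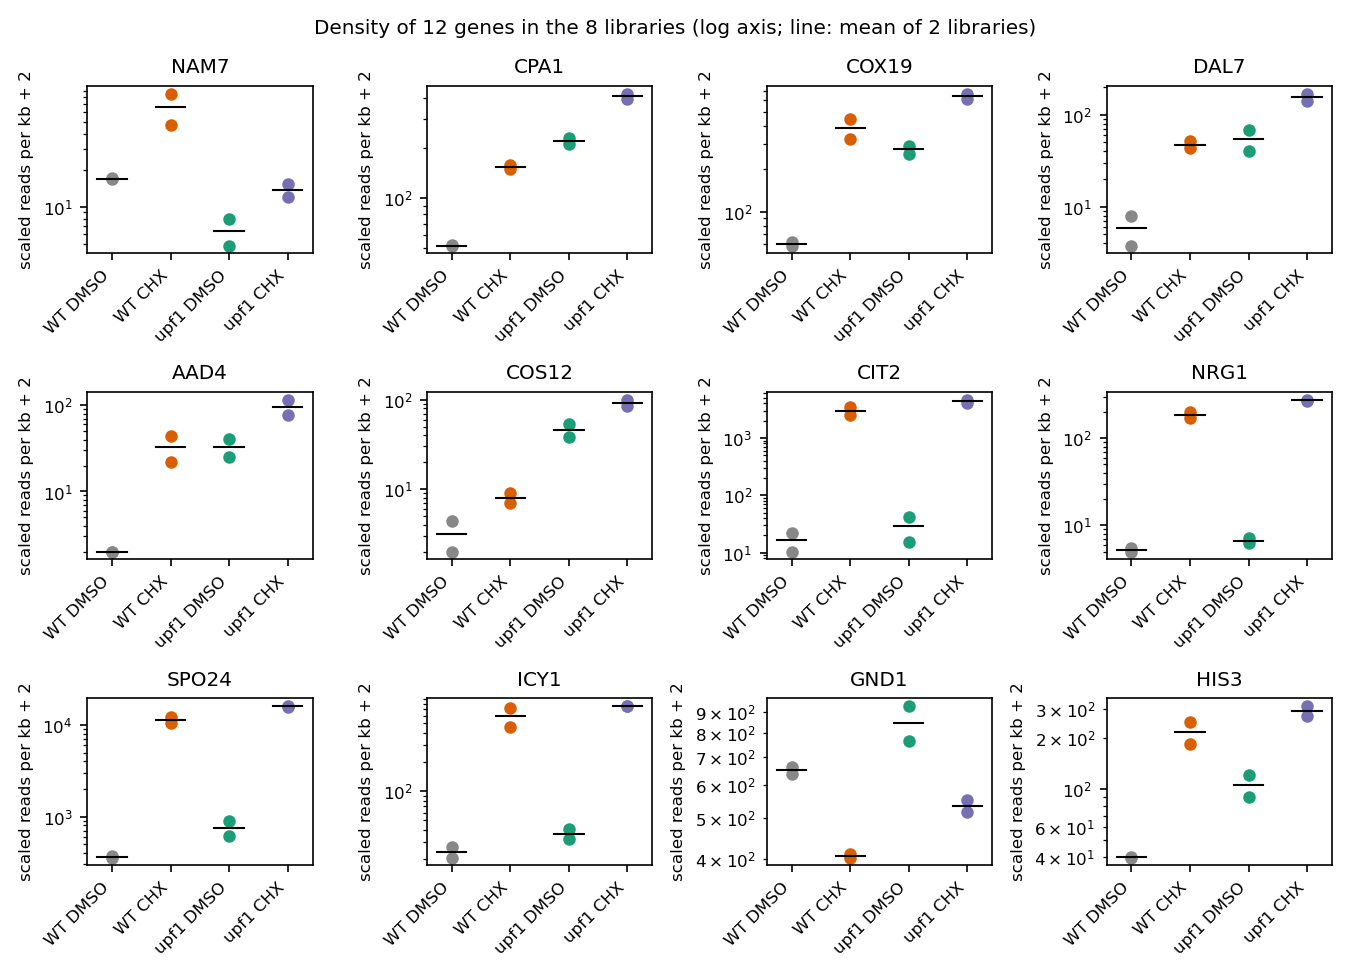
Scaled reads per kb plus 2 of 12 genes in the 8 libraries, on a log axis; lines are means of 2 libraries. CIT2 went from a mean of 14.4 to 2979 on CHX in WT, and CPA1 from 49.9 in WT DMSO to 219 in upf1 DMSO.

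Under CHX few RNAs differed between the genotypes by test. The protein-coding median was 0.58 higher in upf1 (1.50-fold), with a change of the class sum of 0.033 ± 0.114 (1.02-fold), and 3 of 5517 protein-coding genes rose. By limma 5 of all features rose and 4 fell, 2457 had an unadjusted p past the threshold, and voom on recovered reads called 1201 higher and 67 lower. Median scaling took off 0.57 and left 2 higher and 12 lower, without COS12, TCA17 and YOR302W. A fit of only the 4 CHX libraries, the replicate block and a pseudocount 0.25 times as large each called 0 and 0 by limma. A pseudocount 4 times as large gave 106 and 19. COS12 went from 6.03 ± 1.50 to 90.2 ± 11.3, by 3.53 ± 0.408 (adjusted p = 0.0446), with the caution on its copies. TCA17 (YEL048C, chromosome V, 64709 to 65167), a subunit of a Golgi tethering complex, went from 42.9 ± 0.0912 to 167 ± 26.6, by 1.90 ± 0.22 (adjusted p = 0.0446). YOR302W (chromosome XV, 882765 to 882842), the upstream ORF of CPA1, went from 182 ± 3.64 to 497 ± 17.1, by 1.44 ± 0.17 (adjusted p = 0.0459); it was chosen after its values were seen. CPA1 itself and EST3 missed the threshold (1.42 and 1.41, adjusted p = 0.0545 and 0.113). XUT0181 had 13 reads against 0, at least 4.11-fold higher, and tS(AGA)E had 4 against 0. tK(CUU)E2, tK(CUU)I, CUT348 and tR(ACG)E had 0 reads in upf1 against 6, 4, 6 and 3. Leaving out any 1 of the 8 libraries ended all 9 calls, except that XUT0181 stayed called without upf1 CHX replicate 2. With that library out 2 features rose and 4 fell, none of these 4 among the falls above, and with any other library out 0 rose and 0 fell by limma.

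Gene lists differed between the genotypes under CHX only by the preset-correlation test. NMD targets stood 0.63 above the protein-coding median with 0 of 17 called over all features by limma (13 higher without adjustment, 9 by voom) and 11 adjusted over the list alone. Camera gave adjusted p = 0.00202, and adjusted p = 0.503 with an estimated correlation. Proteasome genes stood at 0.23 with 0 of 33 called by limma (24 higher without adjustment, 19 by voom) and 19 adjusted over the list alone (adjusted p = 0.000228, and adjusted p = 0.579 with an estimated correlation); RPN13 and RPN5 had log2 changes of 1.33 and 1.28 (both adjusted p = 0.113). Glycolysis and fermentation stood at -0.86 with 0 of 27 called by limma (11 lower without adjustment, 9 by voom) and 9 lower adjusted over the list alone (camera adjusted p = 5.67e-18, and adjusted p = 0.31 with an estimated correlation). Removing a fitted trend with abundance took the list to -0.31. ENO2 and TDH2 were at -0.53 and -0.54. Phosphate, iron and MATa-specific genes stood at -0.66, -0.42 and -0.52 (adjusted p = 1.26e-06, 8.63e-06 and 0.000649), each with adjusted p = 0.503 with an estimated correlation. Adjusted over the list alone, 2, 3 and 1 of these genes were lower and 2 of the iron genes higher, with PHO89, FET3 and MFA1 at -1.48, -0.76 and -0.71. Ribosomal proteins, histones, sulfur assimilation and mitochondrially encoded genes stood at -0.20, -0.43, -0.19 and -0.43 (adjusted p = 0.0109, 0.026, 0.0413 and 0.0495). With an estimated correlation these had adjusted p = 0.934, 0.742, 0.71 and 0.579, and all 4 calls ended without WT CHX replicate 1 or upf1 CHX replicate 2. Quantile normalization turned the ribosomal protein list to 0.10, past the threshold in the other direction (adjusted p = 0.025). The sulfur call also ended without WT CHX replicate 2, and the mitochondrial call without any 1 of the DMSO libraries. Protein-coding genes as a class stood above other features (adjusted p = 2.44e-14) and CUTs, NUTs and other ORFs under them (adjusted p = 3.93e-19, 4.73e-07 and 8.54e-05). With an estimated correlation these had adjusted p = 0.503, 0.157, 0.503 and 0.219. tRNAs stood at -1.43 and snoRNAs at -0.61 (adjusted p = 6.51e-31 and 4.73e-07). Capped and processed snoRNAs and snRNAs stood at -0.50, -0.80 and -0.77 (adjusted p = 6.95e-05, 3.55e-19 and 2.34e-05, and adjusted p = 0.568, 0.143 and 0.343 with an estimated correlation), and the capped snoRNA call ended without WT CHX replicate 2.

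Whether the CHX response itself depended on UPF1 was tested as an interaction. By the median feature non-coding classes had smaller log2 rises on CHX in upf1 than in WT. Their interactions were -0.57 for XUTs, -0.61 for SUTs, -0.54 for CUTs and -0.42 for NUTs, against -0.01 for protein-coding genes. Camera gave adjusted p = 3.37e-05, 2.54e-06, 0.00406 and 0.000156 for these classes and 1.18e-09 for protein-coding genes, and adjusted p = 0.973 with an estimated correlation for each. The CUT call ended without WT CHX replicate 2, WT DMSO replicate 2 or upf1 DMSO replicate 2. Summed over the class, the XUT interaction was -1.17 ± 0.21, that of SUTs -1.10 ± 0.269 and that of CUTs -0.46 ± 0.185, while that of NUTs, -0.038 ± 0.04, was within its SE of 0. By limma 0 single features passed, 944 had an unadjusted p past the threshold (139 higher and 805 lower), the smallest adjusted p was 0.134, and voom called 0 higher and 1 lower. The features with the smallest p, none past the threshold, were XUT0181 (3.83), NIT1 (-2.64), YCR101C (-2.73) and CUT530 (-3.29). COX19 stood at -1.43 (adjusted p = 0.222). In simulated data with 50 features changed 4-fold, the interaction test found 6, so differences of that size were mostly not detectable with 2 libraries per group.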

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

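The tests of explanations in this part, except the one on the other mating type, were chosen only after the result was seen.

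There were 5 classes that differed between WT and upf1 in their CHX response by the interaction test. Median interactions were -0.57 for XUTs (camera adjusted p = 3.37e-05), -0.61 for SUTs (2.54e-06), -0.54 for CUTs (0.00406), -0.42 for NUTs (0.000156) and -0.01 for protein-coding genes (1.18e-09). With an estimated correlation each had adjusted p = 0.973, and the catalogues overlap. The CUT call ended without WT CHX replicate 2, WT DMSO replicate 2 or upf1 DMSO replicate 2. The protein-coding value was close to 0 and stands out only because the other features lay lower.

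The smaller CHX rise of XUTs in upf1 is one of folds, from a higher DMSO level, as the gain in scaled reads was not smaller. It was weighed against 2 technical explanations. If the pseudocount and the few reads of WT DMSO made it, the ratio of summed XUT reads to summed protein-coding reads, which needs no pseudocount, would show no interaction; it was -1.08 ± 0.1. If a few abundant XUTs made it, leaving out the 20 with the most reads would end it; the value was then -1.04 ± 0.126. Without CHX the XUT sum already stood higher in upf1 than in WT, by 1.705 ± 0.181 on the log2 scale. Whether accumulation of UPF1-sensitive RNAs made that level stays open. The interaction of the XUT to CUT ratio was -0.71 ± 0.106. However, the upf1 DMSO level, on which XUTs and CUTs differed, is part of that value, so it largely restates the pattern. Digestion differences between libraries stay open as well.

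The higher median of protein-coding RNA on CHX and in upf1 was weighed next; in upf1 the class sum changed by only 0.12 ± 0.133 in DMSO and 0.033 ± 0.114 in CHX. A single scale factor per library would raise snRNAs alike. Their median change on CHX minus the protein-coding one was -1.42 ± 0.264 in WT and -1.54 ± 0.264 in upf1, so features did not all move alike. This difference is taken within a library and no factor alters it, so it cannot judge whether the factors set the protein-coding rise. With median scaling the protein-coding median on CHX in WT was -0.004 and the snRNA median -1.395. Less complete digestion in the CHX libraries would raise snoRNAs with processed ends over capped ones; the difference was 0.64 ± 0.363 in WT and 0.67 ± 0.363 in upf1, and -0.34 ± 0.363 for upf1 against WT in DMSO, each within 2 SE of 0, so by snoRNAs the explanations cannot be told apart. Summed reads of tRNAs, which carry 5′ monophosphates, changed on CHX by 1.18 ± 0.152 in WT and 0.99 ± 0.152 in upf1. Both were past the bound set for less complete digestion. In upf1 against WT in DMSO they changed by -0.57 ± 0.152, past the bound set against it. Sums of rRNA, read as a target as well, changed by 0.54 ± 0.321 (within 2 SE of 0), 1.35 ± 0.321 and 0.26 ± 0.321. These SE pool the spread of all 4 groups. With the SE of only the 2 groups compared, rRNA changed on CHX by 0.54 ± 0.215 in WT, beyond 2 SE, and 1.35 ± 0.4 in upf1. On CHX both classes then lie on the side of less complete digestion, so the reading depends on the SE. In upf1 in DMSO they do not pass in the same direction. The explanations cannot be told apart. Stabilisation of capped mRNA by CHX or by loss of UPF1 may contribute and was not tested, as undigested libraries were not analysed here.

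The form of these tests was changed after a first form had been run and its values seen, from medians of levels to medians of values centred per feature, and from summed densities to summed scaled reads. The reason was that a median of levels follows different features in different libraries. The change moved 2 readings. In the first form the snoRNA difference was 0.95 ± 0.317 on CHX in WT and 1.00 ± 0.317 in upf1, beyond 2 SE and as less complete digestion would give, and -0.32 ± 0.317 for upf1 in DMSO. Glycolysis genes against their neighbours stood at -0.39 ± 0.172 in DMSO and, within 2 SE of 0, at -0.23 ± 0.172 in CHX. The other first values were -1.52 ± 0.274 and -1.66 ± 0.274 for snRNAs, -0.94 ± 0.114 and -0.93 ± 0.145 for XUTs with and without the 20, and -0.67 ± 0.105 for XUTs to CUTs. The bound written for the snoRNA test on CHX counted a difference within 2 SE against digestion; it was left open instead, since 0.64 ± 0.363 and the first form lay on the side of digestion.

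Relative to the protein-coding median, glycolysis and fermentation genes and MATa-specific genes stood low in upf1, though their own medians were -0.013 and -0.18 in DMSO and the calls were lost with an estimated correlation (adjusted p = 0.532 and 0.513, and in CHX 0.31 and 0.503). If this were a trend with abundance, glycolysis genes would match protein-coding genes of like density, but their median against the 50 nearest genes was -0.31 ± 0.1 in DMSO and -0.42 ± 0.1 in CHX, the latter resting on the changed form of the test. Removing a fitted trend with abundance took the list from -0.52 to -0.31 in DMSO and from -0.86 to -0.31 in CHX, so the trend accounts for much of the gap, though not for all of it. If cells of the other mating type were mixed in, MF(ALPHA)1 would reach 10% of MFA1. It reached 0.41% in upf1 DMSO and 0% in WT DMSO. Of the other MATalpha genes, SAG1 stood at 20.78 and 13.05 in upf1 DMSO against 6.56 and 3.335 in WT DMSO. STE3 stood at 4.054 and 2.39 against 0.9382 and 0, and MF(ALPHA)2 at 4.451 and 2.625 against 2.576 and 9.165. The MATalpha list was not called in upf1 DMSO (camera adjusted p = 0.845). A biological effect of UPF1 loss on these genes, a difference between cultures in growth, and the lower phosphate and iron lists stay open.

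Ribosomal RNA was left out of the tests. Summed over 8 features it stood at 6.82 ± 0.111 units of 1000 scaled reads in WT DMSO, 10 ± 2.09 in WT CHX, 8.46 ± 3.1 in upf1 DMSO and 20.85 ± 2.37 in upf1 CHX, and in both genotypes each CHX library lay above each DMSO library. RDN37-1 and RDN37-2 carried the sum, and in each genotype both were higher in each CHX library than in each DMSO library. RDN5-1 went from 544.1 and 722.6 to 356.6 and 459.5 scaled reads per kb on CHX in WT. The 21S_rRNA went from 38.76 and 33.91 to 21.44 and 16.6 on CHX in upf1. Whether RDN5-1 and 21S_rRNA carry 5′ monophosphates was not examined, so their falls do not bear on digestion. In upf1 against WT in CHX the rRNA and tRNA sums moved apart, by 1.07 ± 0.321 and -0.76 ± 0.152, so neither alone was read as a measure of digestion.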

How the results depend on the processing

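Voom was chosen only after the result was seen; the other alternatives were planned. Of 1673 class and list results under the alternatives, 1440 kept their direction and side of the threshold, 227 kept the direction only and 6 reversed. Of 2874 results for named genes, 2454 kept both, 388 lost the threshold, 25 gained it and 7 reversed. For named genes median scaling ended 34 calls and reversed 4 changes. With an estimated correlation, 7 of 84 class and list calls passed. The causes of the changes were not tested, except that median scaling and quantile normalization remove a shift of all genes by construction.

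Median scaling gave 947 higher and 305 lower on CHX in WT, 160 and 151 on CHX in upf1, 367 and 92 in upf1 in DMSO, and 2 and 12 in upf1 in CHX. Quantile normalization gave 628 and 551, 186 and 120, and 295 and 79 in the first 3. The replicate block gave 18 lower on CHX in WT and 26 lower on CHX in upf1, and 0 higher and 0 lower for upf1 in CHX. Same-numbered libraries deviated together with correlations of -0.04 to 0.12 over all features and -0.26 to 0.63 over 1698 features above 100 reads, where WT CHX, upf1 DMSO and upf1 CHX deviated together (0.63, 0.308 and 0.323). WT DMSO did not join them and no label names a shared day, so no pairing was taken, and one cannot be excluded for those 3 groups.

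A pseudocount 0.25 times as large gave 10 lower on CHX in upf1, 0 and 0 for upf1 in CHX, and 2 higher and 11 lower for the interaction. A pseudocount 4 times as large gave 827 and 27 for upf1 in DMSO, 106 and 19 for upf1 in CHX, and a correlation of the CHX responses of 0.65. No filter gave 8 and 7 for upf1 in CHX and the stricter filter 0 and 0. No variance trend gave 5 lower on CHX in upf1, 26 lower for upf1 in DMSO, 7 lower for upf1 in CHX, and 2 and 2 for the interaction. Voom gave 1201 and 67 for upf1 in CHX and 1 lower for the interaction. Only the 4 libraries gave 8 lower on CHX in upf1, 114 and 12 for upf1 in DMSO, and 0 and 0 for upf1 in CHX. Robust variances moved no count by over 1.5 times.

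Leaving out 1 library, the lone library being assumed to vary like the other groups, gave 4738 to 7262 higher and 8 to 25 lower on CHX in WT, 2439 to 6907 and 1 to 54 on CHX in upf1, and 194 to 1072 and 11 to 32 for upf1 in DMSO. It gave 0 to 2 and 0 to 4 for upf1 in CHX, and 0 higher and 0 to 1 lower for the interaction. The lowest were without WT CHX replicate 1 for CHX in WT (both counts), without upf1 CHX replicate 1 for CHX in upf1 and without upf1 DMSO replicate 1 for upf1 in DMSO. The correlation of CHX in WT with upf1 in DMSO ranged from 0.392 to 0.626.

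Quantile normalization reversed the glycolysis list on CHX in WT (0.28, adjusted p = 0.417), capped snoRNAs for upf1 in DMSO (0.077, adjusted p = 0.851) and ribosomal proteins for upf1 in CHX (0.10, adjusted p = 0.025). For tRNAs on CHX in WT only the direction given by camera turned with quantile normalization (median 0.33, adjusted p = 0.421, from 0.29). So it did for other ORFs on CHX in upf1, whose median stayed at 0.20 with median scaling (adjusted p = 0.0256) and quantile normalization (0.20, adjusted p = 0.0373). On CHX in WT, CDC19 stood at -0.31 and snR36 at -0.50 with median scaling, and snR36 at -0.65 with quantile normalization. On CHX in upf1, PRE8 stood at -0.019 and FPR2 at -0.15 with median scaling, and FPR2 at -0.064 and LSR1 at 0 with quantile normalization.

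Scaling by spike-in was not run, since the table holds no spike-in rows, and of count-based fits only voom was run, on the recovered reads. The calls are limited by depth and by 2 libraries per group, whose parts were not separated: among 50 features changed 4-fold in simulated data, 21 were found for upf1 against WT in DMSO and 6 for the interaction.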

Other observations

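The gene lists and features in this part were compared by the planned tests, and the features without a list were chosen only after the result was seen.

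The 2-micron plasmid ORF R0010W stood at 109.5 and 73.2 scaled reads per kb in WT DMSO, 612 and 533 in WT CHX, 730 and 568 in upf1 DMSO, and 1160 and 1246 in upf1 CHX. Its log2 changes were 2.64 ± 0.235 on CHX in WT (limma adjusted p = 0.000434), 0.90 ± 0.235 on CHX in upf1 (adjusted p = 0.0146) and 2.82 ± 0.235 in upf1 against WT in DMSO (adjusted p = 0.00275). R0040C changed by 2.94, 1.05 and 2.62 in these comparisons. R0020C and R0030W, on the same plasmid, rose by 1.26 and 1.90 on CHX in WT and were not called in upf1 DMSO (adjusted p = 0.102 and 0.937). SRG1, whose transcription represses SER3, rose by 1.79 ± 0.185 on CHX in WT and by 0.92 ± 0.185 in upf1 DMSO (adjusted p = 0.000531 and 0.0199). ICR1, which crosses the FLO11 promoter, rose by 2.49 ± 0.375 and 2.02 ± 0.375 (adjusted p = 0.00147 and 0.0153). The stable RNAs SCR1, RPR1, TLC1 and NME1 were not called on CHX in WT (adjusted p = 0.196, 0.108, 0.168 and 0.197).

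HIS3, whose gene carries a deletion in BY4741, was read in every library, at 37.8 and 37.6 in WT DMSO, 249 and 183 in WT CHX, 119 and 88.4 in upf1 DMSO, and 270 and 311 in upf1 CHX. Of the MATalpha genes, STE3 stood at 0.94 and 0 in WT DMSO and 26.6 and 21.9 in upf1 CHX, and SAG1 at 6.56 and 3.34 and at 33.6 and 30.2. STE3 had 62 reads in WT CHX against 2 in WT DMSO, a ratio of 22.1 (95% interval 5.87 to 187).

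Of the 33 gene lists, 14 were called by camera in no comparison, with a smallest adjusted p of 0.0503. On CHX in WT limma called higher 14 of 28 cytoplasmic decay genes (13 adjusted over the list alone), 13 of 21 nuclear exosome genes (11 alone), 2 of 7 NMD machinery genes, 16 of 27 RNA polymerase I and III genes and 16 of 31 G1/S genes (15 alone). It called higher 24 of 39 oxidative phosphorylation genes (23 alone), 41 of 56 mitochondrial ribosomal protein genes, 23 of 26 ergosterol genes, 9 of 13 pleiotropic drug resistance genes and 9 of 13 autoregulated mRNAs (10 alone). Of the remaining lists it called higher 2 of 4 MATalpha-specific genes, 10 of 13 haploid and pheromone genes, 12 of 16 meiosis genes and 8 of 13 telomere genes. The relative medians on CHX in WT ran from -0.37 for NMD machinery to 0.43 for meiosis genes. In upf1 against WT in DMSO limma called 5 of the 16 meiosis genes (6 alone) and 3 of the 13 telomere genes (6 alone) higher, and 2 of the 7 NMD machinery genes higher and 1, NAM7 itself, lower.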
